A study of Mus musculus with 12 samples.

How the data were processed

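RNA of 12 samples of sorted mouse bone-marrow progenitors was measured on an Affymetrix mouse expression array, 1 array per sample. Per the labels' protocols, the lineage-negative, c-Kit-positive, Sca-1-positive and Flt3-negative cells were cultured for 24 h in medium with 10% serum, stem cell factor at 50 ng/ml and interleukin 6 at 5 ng/ml. They were then exposed to retrovirus for 4 h with polybrene and kept in fresh medium for 20 h, and the GFP-positive cells were sorted. RNA was extracted with Trizol and a column and amplified in repeated rounds of cDNA synthesis before biotin labelling, per the same protocols. Per the design text, each replicate was a separate sort, transduction and array analysis, so the p-values measure the spread between such experiments.

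The deposited table holds 45101 probe sets on a log2 scale, already summarised and scaled by the authors. The log base was read from the values, which ran from 2.82 to 14.97, and the authors' method of background correction, normalisation and summarisation is not given in the sources used here. Array medians differed by at most 0.17, under the limit of 0.2 set beforehand for adding quantile normalisation, so the values were used as deposited. Such values carry no measure of background, and low values are compressed, so fold changes of dim genes are understated.

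Probe sets were named from the platform annotation given with the data. Of these, 34958 had 1 gene symbol, 932 had several and 9211 had none, 51 of the last being control probe sets; those with several or none were left out of the gene tests, as were all 64 control probe sets. The Entrez identifiers of 34754 single-symbol probe sets were found in the RefSeq gene table, and 0 symbols changed by that match. No genome coordinates are printed. Probe sets with a mean over all arrays above the 40th percentile of probe-set means (5.10 log2 units) were kept, 27022 in all, and each gene was represented by the probe set with the highest mean over all arrays, which left 12918 genes. Columns of per-sample values left unused numbered 0. Cells were grouped by the labels alone, and no array shared its values with another: the SD of the difference between arrays of a group was 0.226 to 0.409, and 1.20 to 1.29 where INV16 replicate 4 was 1 of the pair.

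Before the data were examined, the design was fixed as a limma (version 3.58.1, R version 4.3.3) linear model with a mean for each of the 3 groups over all 12 arrays, with empirical Bayes moderation (9 residual and 2.61 prior degrees of freedom) and Benjamini-Hochberg adjustment over the 12918 genes. A gene was called at an adjusted p under 0.05. All limma, camera and fry tests were two-sided. Also fixed then were 25 gene lists with 546 symbols, 495 of them distinct, of which 458 were named on the array and 407 tested; the smallest list tested had 5 measured genes. The lists hold pathways, cell cycle phases, stress responses and markers of other cell types, were drawn from general knowledge, and overlap: Nfe2, for example, is in the erythroid and in the RUNX1/CBF target list. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 25 lists, with camera at a correlation estimated per list and fry as alternatives. Fry tests whether a list's genes move one way on balance and does not compare them with other genes. None of the lists called by camera was called with the estimated correlation, in any comparison, with or without INV16 replicate 4. When a single array was left out of the 12, it called 4 lists in the ACD mutant against MIB control, each in 1 or 2 of the 12 fits. They were interferon response without ACD mutant replicate 1 (adjusted p = 0.0483), p53 response without that array (0.0483) or MIB control replicate 3 (0.0337), megakaryocyte without MIB control replicate 7 (0.0305) and monocyte and macrophage without MIB control replicate 6 (0.0301).

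The genes named in the text follow a rule fixed at the same time. It takes the 10 called genes with the largest changes up and down whose groups do not overlap, up to 4 called members of each list, the genes Cbfb, Myh11, Runx1, Kit, Flt3 and Cd34 whatever their test, the 10 smallest p-values where fewer than 5 genes are called, and the 3 leading members of each called list. Ly6a, which encodes Sca-1, was also in the rule but is unnamed here and was not analysed. Genes outside the rule are said to be so where they appear.

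After the data were seen, further steps were added. The tests were repeated without INV16 replicate 4 (8 residual and 5.04 prior degrees of freedom). The filter and the choice of probe sets stayed those of all 12 arrays. Genes such as Cma1 and Fcer1a, high only on that array, thus stayed among those tested. The split of the arrays by the BioC and BioB spike-in controls was used as a batch block, with all 12 and with 11 arrays. With 12 arrays INV16 replicate 4 is the only INV16 array of batch B, so the block then rests in part on its deviation. INV16 and MIB control were compared within batch A alone, and the ACD mutant and MIB control within batch B alone. The labels give no scan date or batch.

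The limma fit without a block and camera at its preset correlation were tested on simulated data. There 200 of the 12918 genes were changed by 0.5, 1 or 2 log2. Genes were independent and had the same spread in all groups, whereas replicate 4 widens that of INV16 in the 12 arrays. Fry, the estimated correlation and the batch block were not tested in this way. With 12 arrays 59.7% of genes changed by 1 log2 were recovered in INV16 against MIB control, 53.7% in the ACD mutant against MIB control and 46.3% in INV16 against the ACD mutant. In the 11 arrays without INV16 replicate 4 the shares were 92.5%, 85.1% and 79.1%.

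The alternatives tried were quantile normalisation, centring each array on its median, no filter and a filter at the 60th percentile, all probe sets, the mean of a gene's probe sets, a fit to only the groups compared, an intensity trend, a robust prior, array weights, the replicate number as a block, an adjusted p under 0.10, a minimum of 1.5-fold and leaving out each array in turn. Floors for linear values were planned but had no use, since the values were log2. For the correlation of fold changes against shared controls, 50 draws of unchanged groups were simulated, and other splits of the arrays into groups of the same sizes were fitted, up to 100 per comparison. The draws took genes as independent. The correlation was simulated again with the batch as a block, on the spread within batches; the numbers of genes called in unchanged groups come from fits without the block, on each group's whole spread, and hold no shift between batches. The splits were fitted with the block too. Every list was tested again without each array, and overlaps of called genes were counted again with the MIB control arrays split between the comparisons; the blocked fit of the ACD mutant against MIB control was repeated without each of the 2 controls of batch B; these steps too were added after the data were seen.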

Results

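Gene expression was measured in primitive blood progenitors of mouse bone marrow, which were sorted as lineage-negative cells carrying c-Kit and Sca-1 but not Flt3. The cells were transduced with a retrovirus, and those positive for the green fluorescent marker were sorted and profiled on 1 array per sample after 24 h. The 12 arrays fell into 3 groups. MIB control (5 arrays, replicates 3 to 7) received the empty vector. INV16 (4 arrays, replicates 1 to 4) received the leukaemia fusion of CBFB, a subunit of the core binding factor, with the myosin MYH11. ACD mutant (3 arrays, replicates 1 to 3) received the fusion without its assembly competence domain, a form that the design text calls non-leukemogenic. The array medians lay between 5.62 and 5.79 log2 units and the single values between 2.82 and 14.97. The number of arrays limits the precision of every comparison.

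The arrays also differed in ways that the groups do not name. The difference between the bacterial spike-in controls BioC and BioB was 1.07 to 1.21 log2 in MIB control replicates 3 to 5 and INV16 replicates 1 to 3, here called batch A. It was -0.11 to 0.07 in the other 6 arrays, batch B, which held MIB control replicates 6 and 7, INV16 replicate 4 and all 3 ACD mutant arrays. Batch A thus held no ACD mutant array, and without INV16 replicate 4 batch B held no INV16 array. Within batch B the level of BioB was 8.57 and 8.76 in MIB control replicates 6 and 7. It was 7.71 in INV16 replicate 4 and 7.13 to 7.49 in the ACD mutant arrays. The batch block leaves this difference between ACD mutant and MIB control in place. The 3' minus 5' difference of Gapdh, a measure of RNA integrity, was 3.64 log2 in INV16 replicate 4, 3.17 in ACD mutant replicate 1 and 1.10 to 1.98 in the other 10 arrays.

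INV16 replicate 4 stood apart from the other 11 arrays. Its correlation with them across probe sets, which are not independent replicates, was 0.895 to 0.917, against 0.985 to 0.996 among the others. Its mast cell genes were far higher. The IgE receptor chain Fcer1a measured 13.31 against 4.27 to 5.74 on the other arrays, the chymase Cma1 12.70 against 4.50 to 5.27, and the cytokine Il4 10.09 against 4.41 to 5.18. Genes of primitive progenitors went different ways. The homeobox gene Hoxa9 measured 4.39 against 12.46 ± 0.09 (SD, n = 3) on the other INV16 arrays. The transcription factor Sox4 measured 3.51 against 9.97 to 11.70 on the other 11 arrays, and the surface marker Cd34 7.39 against 11.16 to 12.35. The receptor Kit, at 10.99, lay within the 10.26 to 11.43 of the others, and the transcription factor Gata2, at 11.74, above their 9.67 to 11.26. Against the other INV16 arrays the fixed list of long-term stem cell genes had a median deviation of -0.82 with 11 of 29 members higher, and Hox and Meis genes one of 0.10 with 6 of 10 higher and a mean of -0.86. Xist, transcribed from the inactive X chromosome of female mice, measured 12.68 against 6.02 to 6.48, and the Y-linked Eif2s3y 3.57 against 10.07 to 10.78. These genes, Cma1, Cd34 and Kit apart, were chosen after their values were seen. Each comparison is therefore given with all 12 arrays, as planned, and again without INV16 replicate 4, a step added after the data were seen.

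**Figure D1:**
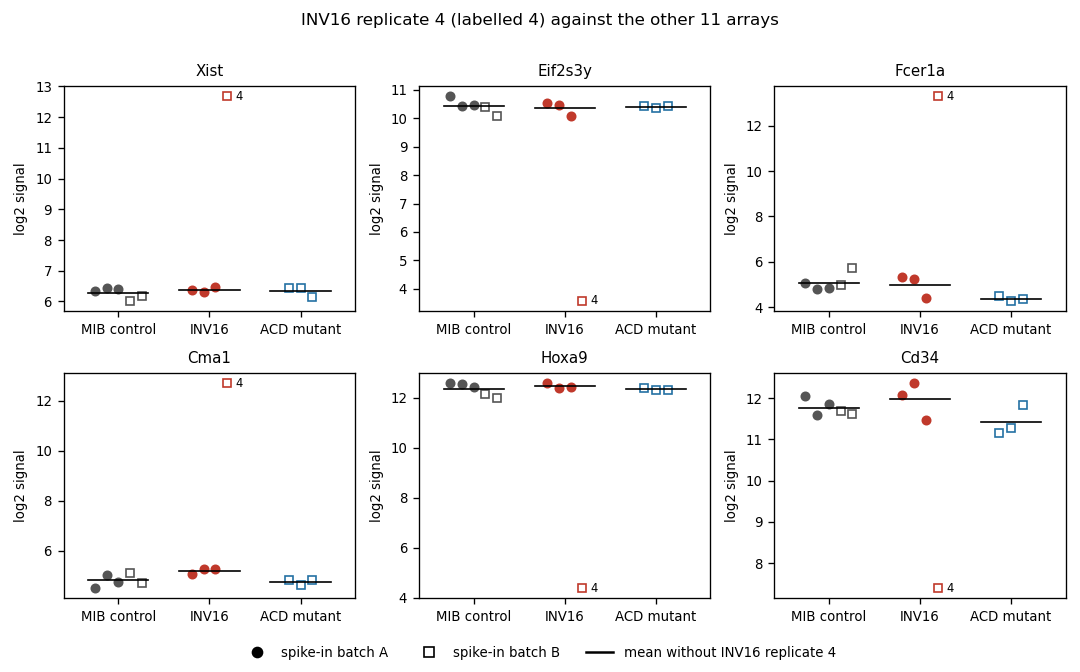
Log2 expression (vertical axis) of Xist, Eif2s3y, Fcer1a, Cma1, Hoxa9 and Cd34 on each array of the MIB control, INV16 and ACD mutant groups (horizontal axis); filled circles are spike-in batch A, open squares batch B, the mark 4 is INV16 replicate 4 and the line is the group mean without it. INV16 replicate 4 lies at 12.68 for Xist, where the other 11 arrays lie at 6.02 to 6.48, and at 7.39 for Cd34, where they lie at 11.16 to 12.35.

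Transcripts of the mouse genes joined in the fusion passed the test in no comparison. Cbfb measured 12.04 ± 0.67 (SD, n = 4) in INV16 and 12.42 ± 0.19 (SD, n = 5) in MIB control, a log2 fold change of -0.38 (SE 0.25, limma adjusted p = 0.406). Leaving out INV16 replicate 4 gave -0.05 (SE 0.12, adjusted p = 0.892), and in the ACD mutant against MIB control -0.30 (SE 0.12, adjusted p = 0.179). Both mouse Myh11 probe sets lay below the expression filter, with group means of 3.73 to 4.47. The mouse probe sets may not detect the transgenes, so these values check neither the presence nor the level of the fusion. The Cbfb partner Runx1 and the surface markers Kit, Flt3 and Cd34 passed the test in no comparison, with or without INV16 replicate 4. Runx1 was 1.03 log2 higher in the ACD mutant than in MIB control without that array (SE 0.35, adjusted p = 0.128). The 6 Runx1 probe sets disagreed: in INV16 against the ACD mutant the set used differed by -0.73 and another by 0.02.

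The comparison of INV16 with MIB control asks which genes the fusion changes within 24 h of its introduction. The transcription factor Runx3, a relative of Runx1 that also pairs with CBFB, fell 2.98-fold, from 10.19 ± 0.33 (SD, n = 5) in MIB control to 8.62 ± 0.35 (SD, n = 4) in INV16 (log2 fold change -1.57, SE 0.20, adjusted p = 0.0145). Gse1, which encodes a partner of a histone demethylase complex, fell 2.91-fold, from 9.12 ± 0.12 to 7.58 ± 0.30 (log2 fold change -1.54, SE 0.15, adjusted p = 0.00618). The small GTPase Gem fell 8.24-fold (log2 fold change -3.04, SE 0.47, adjusted p = 0.0371). The iron-sensing receptor Tfr2 fell by 1.70 on the log2 scale (SE 0.25, adjusted p = 0.0371), the fucosyltransferase Fut7, which makes selectin ligands, by 1.43 (adjusted p = 0.0142), and Mn1, a transcriptional cofactor studied in leukaemia, by 0.82 (SE 0.13, adjusted p = 0.0371). The transcription factor Klf3 was the only gene called higher, by 0.99 log2 (9.04 ± 0.29, n = 4, against 8.05 ± 0.25, n = 5; SE 0.16, adjusted p = 0.0430). In all, limma called 20 of 12918 genes in the 12 arrays, 1 higher and 19 lower. Btnl9, Spns3, Med7, Csgalnact2 and Foxred2 were also lower, by 1.02 to 1.51 log2. The other Runx3 probe set, at a mean of 6.21 in MIB control, differed by -0.02, those of Gse1 by -0.98 and -0.29, and the 5 others of Klf3 by 0.11 to 0.77. The count was 1 without MIB control replicate 5, MIB control replicate 7 or INV16 replicate 1, 2 without MIB control replicate 6 and 4 without any 1 of the ACD mutant arrays. It was 10, 12 and 13 without MIB control replicate 3, INV16 replicate 2 and MIB control replicate 4, and 219 without INV16 replicate 4. Gse1 kept its call without each of the 12 arrays in turn, and Runx3 lost it without MIB control replicate 5, MIB control replicate 7 or INV16 replicate 1. Gem, Klf3 and Tfr2 kept theirs in 2, 3 and 4 of these 12 fits. After quantile normalisation Runx3 and Gem (each at adjusted p = 0.0600), Klf3 (0.0668) and Tfr2 (0.0697) lost the call, as they did in the fit to only the 2 groups (0.104, 0.159, 0.190 and 0.159). In groups simulated without change, each at its own spread, which replicate 4 widens in INV16, limma called a mean of 48.1 genes (highest 82). Unlike the data, that simulation spreads all INV16 arrays alike.

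When INV16 replicate 4 was left out, all 20 genes were called again in the same direction. They were among 219 genes, 81 higher and 138 lower. After quantile normalisation the split was 103 higher and 114 lower. The semaphorin and VEGF receptor Nrp1 rose 3.06-fold, from 7.51 ± 0.48 (SD, n = 5) to 9.13 ± 0.21 (SD, n = 3; log2 fold change 1.61, SE 0.24, adjusted p = 0.00631). The cytokine Il6, itself present in the medium, rose 2.90-fold, from 5.21 ± 0.36 to 6.74 ± 0.18 (SE of the log2 fold change 0.20, adjusted p = 0.00353). The growth factor Vegfc rose by 1.59 log2 (adjusted p = 0.0107) and the endocytic adaptor Dab2 by 1.41 (adjusted p = 0.00815). The transglutaminase subunit F13a1 rose by 1.61 (adjusted p = 0.0169), Hdac9 by 1.31 and Ammecr1 by 1.34. The lymphoid DNA polymerase Dntt was 3.04 log2 higher (9.88 ± 1.85, n = 3, against 6.84 ± 0.47, n = 5; adjusted p = 0.0227). Sh3d19, at 1.33 log2 with another probe set at 0.19, kept its call in 7 of 22 other settings. The genes that were lower included the sphingosine receptor S1pr3 (6.60 ± 0.18, n = 3, against 8.23 ± 0.29, n = 5; log2 fold change -1.63, SE 0.16, adjusted p = 0.000589). The erythroid and megakaryocyte transcription factor Nfe2 was lower as well (9.16 ± 0.17 against 10.71 ± 0.52; -1.55, SE 0.23, adjusted p = 0.00634), and so was the neutrophil protein S100a8 (-3.08, SE 0.55, adjusted p = 0.0144). Also lower were Ffar2 (-1.56, adjusted p = 0.00268), Tuba8 (-1.35, adjusted p = 0.0132) and cyclin D1, Ccnd1 (-1.35, SE 0.27, adjusted p = 0.0252). Another Dab2 probe set differed by 0.13 and another S1pr3 set by -0.59. With the spike-in batch as a block, 148 genes were called, 118 of them among the 219. Runx3 (-1.85, adjusted p = 0.00176), Gse1 (-1.38, adjusted p = 0.00205), Nrp1 (1.40, adjusted p = 0.0178) and Il6 (1.61, adjusted p = 0.00672) kept their call, and Dntt (2.89, adjusted p = 0.0642) and Sh3d19 (1.11, adjusted p = 0.125) lost it. Within batch A alone, which held 3 arrays of each group, 30 genes were called, 7 higher and 23 lower. Leaving out a further array gave 29 genes (INV16 replicate 1), 66 (INV16 replicate 2), 118 (MIB control replicate 5), 145 (MIB control replicate 6) and 332 (MIB control replicate 4). Runx3, Gse1, Gem, S1pr3, Il6, Dab2 and Ffar2 kept their call without each of the 11 arrays in turn, and Nrp1 and Nfe2 lost it without INV16 replicate 1. Dntt, Vegfc, F13a1, Hdac9, Ammecr1, S100a8 and Tuba8 lost it without INV16 replicate 1 or 2, and Ccnd1 without these or MIB control replicate 5. In the fit to only the 2 groups Dntt, F13a1, Hdac9, Ccnd1 and Sh3d19 lost the call.

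**Figure D2:**
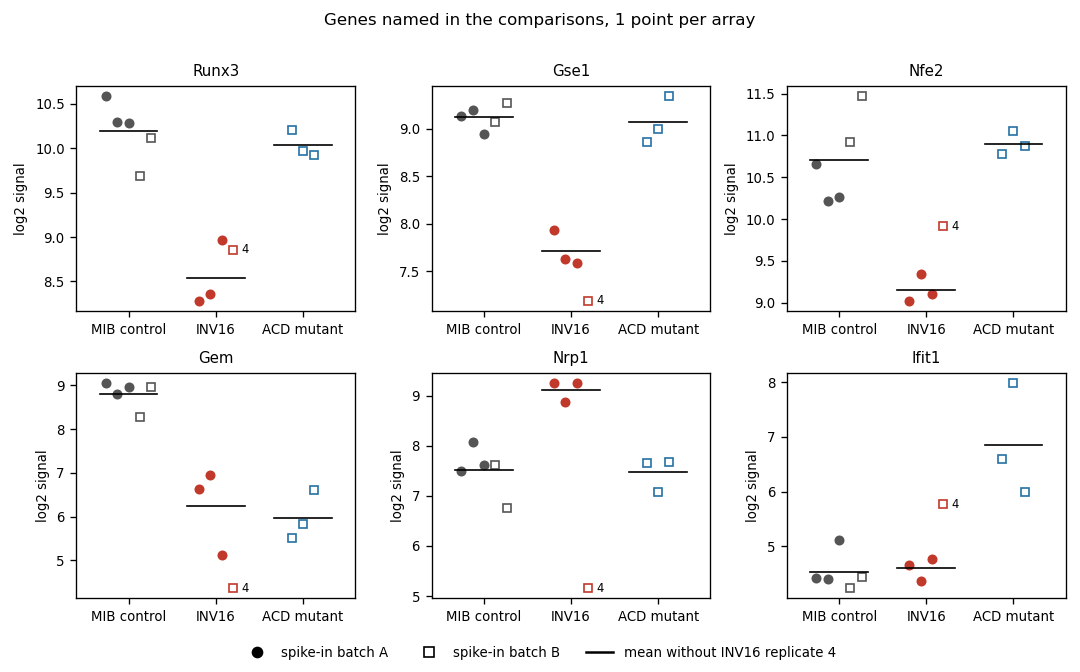
Log2 expression (vertical axis) of Runx3, Gse1, Nfe2, Gem, Nrp1 and Ifit1 on each array of the 3 groups (horizontal axis); filled circles are spike-in batch A, open squares batch B, the mark 4 is INV16 replicate 4 and the line is the group mean without it. Runx3 and Gse1 have means of 8.54 and 7.71 in INV16 without replicate 4, against 10.19 and 9.12 in MIB control, and replicate 4 measured 8.86 and 7.19.

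Several of the gene lists fixed beforehand held members that changed in INV16 without INV16 replicate 4. Of 13 measured genes studied in CBFB-MYH11 leukaemia, 0 were higher and 3 lower, and adjusted over the list alone 0 were higher and 5 lower. The 3 were Mn1 (-0.82, adjusted p = 0.00953), the survival factor Bcl2 (-0.70, adjusted p = 0.0252) and the granulocyte factor Cebpa (-0.91, adjusted p = 0.0477), and the last was lost with the batch as a block (-0.70, adjusted p = 0.116). Of 19 earlier RUNX1/CBF targets 3 were lower (Runx3, Nfe2 and Cebpa), and adjusted over the list alone 1 was higher and 5 lower; the list's median log2 fold change was -0.34 and within batch A -0.27. Among 18 lymphoid genes Dntt and Gata3 (0.99, adjusted p = 0.0344) rose and Nkg7 (-0.73, adjusted p = 0.0150) fell, and adjusted over the list alone 3 were higher and 3 lower. Of 29 long-term stem cell genes Procr (1.48, SE 0.30, adjusted p = 0.0252) and Esam (0.95, adjusted p = 0.0477) rose, and adjusted over the list alone 2 were higher and 2 lower. Esam kept its call in 9 of 22 other settings, as did Cebpa. In the CBF complex and ETO family the corepressor Tle1 rose (1.11, SE 0.19, adjusted p = 0.0113) while Runx3 fell, and among megakaryocyte genes Selp rose (0.95, adjusted p = 0.0122) while Cd9 fell (-0.98, adjusted p = 0.0418). Single members also passed in other lists: the dendritic cell gene Tcf4 (0.75, adjusted p = 0.0169), the DNA repair gene Palb2 (-0.57, adjusted p = 0.0270), the mast cell gene Rab44 (-0.54, adjusted p = 0.0350) and the stromal gene Pdgfrb (-1.10, adjusted p = 0.0132). With the batch as a block Tcf4 (adjusted p = 0.0524), Palb2 (0.0554), Gata3 (0.0904), Rab44 (0.0884) and Cd9 (0.107) lost the call. Bcl2, Cebpa, Procr, Esam, Gata3, Palb2, Rab44 and Cd9 lost it in the fit to only the 2 groups.

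As whole lists, camera called 6 of 25 with all 12 arrays. S phase and DNA replication (29 genes, median log2 fold change -0.66, adjusted p = 4.94e-05), DNA repair (29 genes, -0.34, 0.000804), G2 and mitosis (26 genes, -0.61, 0.000838) and ribosome biogenesis and Myc targets (19 genes, -0.52, 0.000804) were lower. Immediate early and handling stress genes (13 genes, 0.59, 0.00232) and mast cell, basophil and eosinophil genes (13 genes, 0.57, 0.0456) were higher. Each had adjusted p = 0.703 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone. The members with the largest statistics, none of which passed, included Uhrf1 (-1.36, adjusted p = 0.301), E2f1 (-0.58, adjusted p = 0.259), Ccna2 (-0.61, adjusted p = 0.349), Wdr12 (-0.88, adjusted p = 0.312), Jun (1.97, adjusted p = 0.304), Hdc (1.64, adjusted p = 0.346) and Cma1 (2.25, adjusted p = 0.368). INV16 replicate 4 deviated from the other INV16 arrays in the same lists, with a median of -1.83 log2 for S phase, -2.24 for G2 and mitosis, 2.86 for immediate early and 4.18 for mast cell genes. Without it camera called 0 of the 25 lists (6 at unadjusted p under 0.05), with 0 by an estimated correlation and 1 by fry, DNA repair (-0.18, adjusted p = 0.0247). This 0 rested on single arrays. Camera called DNA repair when INV16 replicate 1 was left out, and DNA repair, monocyte and macrophage (-0.39) and S phase genes (-0.12) when MIB control replicate 7 was. Leaving out INV16 replicate 3 gave 10 lists at an adjusted p of 0.0342 to 0.0427: DNA repair (median -0.15), monocyte and macrophage (-0.39), RUNX1/CBF targets (-0.39), cholesterol synthesis (0.23), immediate early (0.19), p53 response (0.18), inflammatory cytokines (0.17), sort markers (0.17), lymphoid (0.06) and long-term stem cell genes (0.06). None of these was called with an estimated correlation (adjusted p = 0.456 to adjusted p = 0.7103). In the full 11 arrays the mast cell list turned to -0.18, and it also lost its call without any 1 of MIB control replicates 3 to 6. With the batch as a block it called DNA repair (-0.15, adjusted p = 0.0192) and S phase (-0.12, adjusted p = 0.0192), with adjusted p = 0.731 with an estimated correlation.

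The comparison of the ACD mutant with MIB control asks what the fusion changes when it lacks the assembly domain. Interferon response genes were higher in the ACD mutant: 22 of 23 measured members lay above 0, with a median log2 fold change of 0.53 (camera adjusted p = 3.2e-12). The call was lost at an adjusted p = 0.106 with an estimated correlation. The height of the list rested heavily on ACD mutant replicate 2: the mean of its members lay 1.22 log2 above the MIB control mean there, 0.47 and 0.45 in replicates 1 and 3, and 0.34 in MIB control replicate 5. Leaving out ACD mutant replicate 2 gave a median of 0.30 (adjusted p = 1.11e-07, adjusted p = 0.0617 with an estimated correlation). The antiviral gene Ifit1 measured 6.85 ± 1.02 (SD, n = 3) against 4.53 ± 0.34 (SD, n = 5), a log2 fold change of 2.33 (SE 0.42, adjusted p = 0.320), and Oasl2 and Rtp4 were 1.99 (adjusted p = 0.432) and 2.10 log2 higher. The p53 response list was also higher (20 genes, median 0.41, adjusted p = 4.12e-05, adjusted p = 0.0879 with an estimated correlation), with Sesn2 at 0.67, Ccng1 at 0.53 and Zmat3 at 0.94 log2, none of which passed. Over single genes limma called 0 of 12918 in the 12 arrays, with 892 at unadjusted p under 0.05, and the count was 220 without INV16 replicate 4. The 10 genes with the smallest p, none passing, were Atf7 (1.18 log2, SE 0.17, adjusted p = 0.276), Zfp825, Snhg12, Ifit1, Gem (-2.83, SE 0.51, adjusted p = 0.320), Ptcd1, Oasl2, Cd33, Nedd4 and Tnfsf13os. Other probe sets past the filter differed by only -0.11 for Atf7, -0.17 for Ptcd1, 0.04 and 0.05 for Nedd4 and 0.05 for Tnfsf13os. Adjusted over the list alone, 8 interferon genes and 1 p53 gene were higher and 0 of either were lower.

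INV16 replicate 4 belongs to neither group but adds to the shared spread, and without it limma called 220 genes, 128 higher and 92 lower. The myeloid receptor Cd300lb rose 5.19-fold, from 6.81 ± 0.61 (SD, n = 5) to 9.19 ± 0.17 (SD, n = 3; log2 fold change 2.38, SE 0.28, adjusted p = 0.0113). Of the 23 interferon genes 4 rose and 0 fell, and adjusted over the list alone 13 rose and 0 fell. The 4 were Ifit1 (2.33, SE 0.34, adjusted p = 0.0150), Oasl2 (1.99, SE 0.34, adjusted p = 0.0204), the GTPase Gbp2 (0.75, adjusted p = 0.0427) and Rtp4 (2.10, SE 0.49, adjusted p = 0.0498). Of 20 p53 response genes 3 rose, namely Perp (1.11, adjusted p = 0.0327), Sesn2 (0.67, adjusted p = 0.0360) and the pro-apoptotic Bbc3 (0.66, adjusted p = 0.0364), and adjusted over the list alone 10 rose and 1 fell. In the fit to only the 2 groups Perp, Sesn2, Bbc3, Gbp2 and Rtp4 lost the call, while Ifit1 and Oasl2 kept it. Another Sesn2 probe set differed by 0.10. The histamine enzyme Hdc (1.56, adjusted p = 0.0150), the GTPase Iigp1 (1.65, adjusted p = 0.0364), the cannabinoid receptor Cnr2 (1.49), the cytokine receptor Csf2rb2 (1.55), Pcp4l1 (1.46), Zfp467 (1.39) and Kcnj5 (1.35) were also higher. Gem fell to 5.98 ± 0.56 (n = 3) from 8.81 ± 0.31 (n = 5; log2 fold change -2.83, SE 0.35, adjusted p = 0.0113). The genes Ndrg1 (-1.28), Alyref (-1.24), Mid1 (-1.08), Aarsd1 (-1.02), Slc6a15 (-0.99), Ccnt2 (-0.98), Zc3h7a (-0.98), Dipk1b (-0.96) and 9030619P08Rik (-1.30) were lower. Some had other probe sets that disagreed: those of Ccnt2 differed by 0.02, -0.33 and -0.38, that of Zc3h7a by 0.006 and that of Alyref by -0.18, and Zfp467 had one at 0.35. With the batch as a block, which rests on batch B alone for this comparison, 20 genes were called, 11 of them among the 220. They included Cd300lb (2.44, adjusted p = 0.0327), Ifit1 (2.51, adjusted p = 0.0456), Sesn2 (0.85, adjusted p = 0.0456), Selp (1.43, adjusted p = 0.00851) and Gem (-2.64, adjusted p = 0.0456). The blocked count was 25 without MIB control replicate 6 and 1 without MIB control replicate 7, the only controls in batch B. Alyref (-1.61) and Aarsd1 (-1.09) kept their call as well. The interferon genes Oasl2 (adjusted p = 0.0744), Rtp4 (0.107) and Gbp2 (0.141) and the p53 genes Perp (0.102) and Bbc3 (0.142) lost it. So did Hdc, Iigp1, Cnr2, Csf2rb2, Pcp4l1, Zfp467, Kcnj5, Ndrg1, Mid1, Slc6a15, Ccnt2, Zc3h7a, Dipk1b and 9030619P08Rik, at an adjusted p of 0.0664 (Ndrg1) to 0.216 (Zc3h7a). Without ACD mutant replicate 1, the array with the raised Gapdh difference, 3 genes were called. The count was 5 without ACD mutant replicate 2, 32 without MIB control replicate 5, 102 without INV16 replicate 1, 116 without MIB control replicate 3 and 591 without MIB control replicate 7. Cd300lb kept its call in each, and Ifit1 lost it without ACD mutant replicate 1.

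As lists, camera called 6 of 25 without INV16 replicate 4. Interferon response (adjusted p = 2.38e-09, adjusted p = 0.373 with an estimated correlation) and p53 response (adjusted p = 9.28e-05, adjusted p = 0.323 with an estimated correlation) were higher, and with the batch as a block their medians were 0.61 (adjusted p = 8.42e-09) and 0.42 (adjusted p = 0.000102). Without ACD mutant replicate 1 the interferon median was 0.68, and without ACD mutant replicate 2 it was 0.30 (adjusted p = 3.92e-06, adjusted p = 0.279 with an estimated correlation). G2 and mitosis genes were lower (26 genes, median -0.16, adjusted p = 0.000901, adjusted p = 0.323 with an estimated correlation), with the kinase Aurka at -0.54 (adjusted p = 0.0484). Adjusted over the list alone 0 were higher and 6 lower, and the blocked median was -0.11 (adjusted p = 0.0401). The megakaryocyte (15 genes, 0.64, adjusted p = 9.56e-05, adjusted p = 0.543 with an estimated correlation), monocyte and macrophage (18 genes, 0.36, adjusted p = 0.00764, adjusted p = 0.839 with an estimated correlation) and long-term stem cell lists (29 genes, 0.23, adjusted p = 0.0127, adjusted p = 0.839 with an estimated correlation) were higher. Their blocked medians were 0.15 (adjusted p = 0.225), 0.21 (adjusted p = 0.334) and 0.05 (adjusted p = 0.529), and the MIB control arrays of batch B exceeded those of batch A by 0.86, 0.17 and 0.34 in the same lists. These values rested on single arrays, since the controls of batch B, replicates 6 and 7, differed: their list means lay at 0.003 and 0.90 for megakaryocyte, 0.60 and -0.30 for monocyte and -0.005 and 0.33 for stem cell genes. Without replicate 7 the blocked medians were 0.71 (adjusted p = 3.95e-08, adjusted p = 0.117 with an estimated correlation), -0.24 (0.0208 and 0.371) and 0.27 (0.00216 and 0.514). Without replicate 6 they were -0.27 (adjusted p = 0.123), 0.70 (adjusted p = 2.82e-08, adjusted p = 0.0971 with an estimated correlation) and -0.03 (0.361). The monocyte list was thus called lower without one of these controls and higher without the other. At the preset correlation the interferon list stayed called without replicate 6 (0.60) or 7 (0.61), as did the p53 list (0.34 and 0.52). Camera with an estimated correlation did not call them (adjusted p = 0.7501 and 0.3712 for interferon, 0.5858 and 0.2037 for p53). G2 and mitosis (-0.05) was not called without replicate 6. The block also called neutrophil granule (19 genes, -0.19, adjusted p = 0.0443) and ribosome biogenesis genes (19 genes, -0.22, adjusted p = 0.0401) lower, each at an adjusted p = 0.881 with an estimated correlation. Leaving out replicate 7 gave -0.61 (adjusted p = 4.31e-13, adjusted p = 0.2037 with an estimated correlation) and -0.29 (adjusted p = 0.00101, adjusted p = 0.4965 with an estimated correlation). Leaving out replicate 6 gave 0.10 and -0.10, neither called. Called only without replicate 7 were mast cell genes (0.15, adjusted p = 0.0209), and only without replicate 6 cholesterol synthesis (-0.31) and erythroid genes (-0.20, each at adjusted p = 0.00220). Camera with an estimated correlation called none of these (adjusted p = 0.4965, 0.8245 and 0.1293). Members that passed were the adhesion molecule Selp (1.14, adjusted p = 0.0150) and the stem cell marker Slamf1 (1.20, adjusted p = 0.0378), while Mmrn1 (0.81, adjusted p = 0.0568), Csf1r (0.98, adjusted p = 0.156) and Mecom (0.58, adjusted p = 0.101) did not. Another Selp probe set differed by 0.35, another of Csf1r by 0.19 and another of Mecom by -0.04. With the batch as a block Aurka (adjusted p = 0.168) and Slamf1 (adjusted p = 0.153) lost the call. Without MIB control replicate 7 the megakaryocyte median was 0.96 and the monocyte list lost its call, and the stem cell list lost its call without MIB control replicate 5 or ACD mutant replicate 2 or 3. Adjusted over the list alone 6 megakaryocyte genes were higher and 0 lower. With all 12 arrays the megakaryocyte (adjusted p = 0.00107, adjusted p = 0.490 with an estimated correlation) and monocyte lists (adjusted p = 0.0205, adjusted p = 0.648 with an estimated correlation) were called too, and fry called interferon and p53 only.

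**Figure D3:**
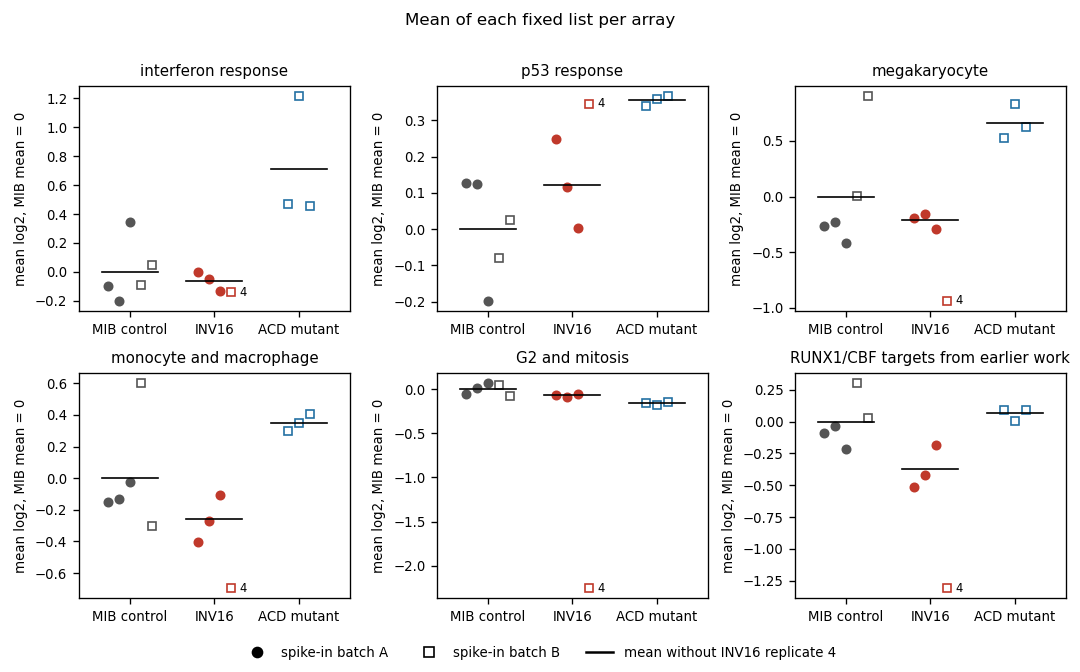
Mean log2 expression of 6 gene lists relative to the MIB control mean (vertical axis) on each array of the 3 groups (horizontal axis); filled circles are spike-in batch A, open squares batch B, the mark 4 is INV16 replicate 4 and the line is the group mean without it. The interferon list has a median log2 fold change of 0.53 in the ACD mutant against MIB control, with ACD mutant replicate 2 at 1.22, and the 2 MIB control arrays of batch B lie at 0.003 (replicate 6) and 0.90 (replicate 7) for the megakaryocyte list.

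The comparison of INV16 with the ACD mutant asks what depends on the assembly domain. A difference here can come from either group, so its side is read from the comparisons with MIB control. With all 12 arrays limma called 5 genes, all lower in INV16. Fam43a fell from 7.77 ± 0.27 (SD, n = 3) in the ACD mutant to 6.16 ± 0.18 (SD, n = 4) in INV16 (log2 fold change -1.61, SE 0.16, adjusted p = 0.00671). Gse1 (-1.48, SE 0.18, adjusted p = 0.0136), Foxred2 (-1.16, SE 0.14, adjusted p = 0.0136), the kinase Prkd2 (-1.08, SE 0.15, adjusted p = 0.0426) and the mechanosensitive channel Piezo1 (-0.91, SE 0.12, adjusted p = 0.0297) were the others. With the batch as a block 4 genes were called, namely Btnl9, Fam43a, Gse1 and Foxred2, and Prkd2 and Piezo1 lost the call (each at adjusted p = 0.0787); Piezo1 lost it after quantile normalisation as well (adjusted p = 0.125). The batch block here rests in part on INV16 replicate 4, the only INV16 array beside the ACD mutant arrays in batch B. Other probe sets of Gse1 differed by -0.999 and -0.10, and 1 of 3 of Prkd2 by -0.32. In groups simulated without change, each at its own spread, limma called a mean of 11.98 genes (highest 33), with all INV16 arrays spread alike, unlike the data. Runx3, at -1.41 (SE 0.22), had an adjusted p = 0.0614. The count was 0 without ACD mutant replicate 1, 1 without ACD mutant replicate 2 or 3, 2 without INV16 replicate 2, 3 without INV16 replicate 1 or MIB control replicate 5, 10 without MIB control replicate 7 and 267 without INV16 replicate 4. Camera called 12 of 25 lists, led by interferon response (23 genes, median -0.68, adjusted p = 1.62e-05, adjusted p = 0.402 with an estimated correlation), of which 0 members were higher and 7 lower adjusted over the list alone. The megakaryocyte (15 genes, -0.87, adjusted p = 0.00187), monocyte and macrophage (18 genes, -0.67, adjusted p = 0.00573), RUNX1/CBF target (19 genes, -0.78, adjusted p = 0.00907), cholesterol synthesis (16 genes, -0.58, adjusted p = 0.0237), CBFB-MYH11 leukaemia (13 genes, -0.30, adjusted p = 0.0237) and long-term stem cell lists (29 genes, -0.40, adjusted p = 0.0469) were lower. Lower as well were S phase (-0.55, adjusted p = 0.000959), DNA repair (-0.40, adjusted p = 0.00187), ribosome biogenesis (-0.45, adjusted p = 0.0139) and G2 and mitosis (-0.47, adjusted p = 0.0237). Immediate early genes were higher (0.75, adjusted p = 0.00154). None of these lists was called with an estimated correlation (adjusted p = 0.402 to adjusted p = 0.717), and fry called 3. Leaving out INV16 replicate 4 ended the calls of S phase (-0.04), DNA repair (-0.14), cholesterol synthesis (-0.20), ribosome biogenesis (0.03), immediate early (0.11) and long-term stem cell genes (-0.31), and G2 and mitosis turned to 0.13. The interferon median was -0.38 without ACD mutant replicate 2. The cholesterol, ribosome, leukaemia and stem cell lists each also lost the call without at least 1 other array.

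In the 11 arrays without INV16 replicate 4 the 5 genes were called again, in the same direction. They were among 267 genes, 40 higher and 227 lower. The interferon receptor chain Ifngr2 measured 6.46 ± 0.21 (SD, n = 3) in INV16 against 8.45 ± 0.15 (SD, n = 3) in the ACD mutant (log2 fold change -1.99, SE 0.28, adjusted p = 0.00567), with another probe set at -0.57. Nfe2 measured 9.16 ± 0.17 against 10.90 ± 0.14 (-1.74, SE 0.26, adjusted p = 0.00721) and Runx3 8.54 ± 0.38 against 10.03 ± 0.15 (-1.49, SE 0.22, adjusted p = 0.00611). Ifit1 (-2.25, SE 0.38, adjusted p = 0.0118), Usp18 (-2.17, adjusted p = 0.0202) and Oasl2 (-2.07, adjusted p = 0.0193) were lower. So were the transglutaminase Tgm2 (-2.43, SE 0.46, adjusted p = 0.0202) and the platelet adhesion protein Vwf (-2.23, SE 0.53, adjusted p = 0.0485). The mast cell genes Ms4a2 (-2.01, adjusted p = 0.0418) and Cpa3 (-1.45, adjusted p = 0.0379), Iigp1 (-1.70) and Cd300lb (-1.56) were lower too. The membrane protein Tm4sf1 was higher in INV16 (6.94 ± 0.38 against 5.56 ± 0.14; 1.37, SE 0.17, adjusted p = 0.00353). Also higher were Nrp1 (1.65, SE 0.27, adjusted p = 0.0101), Il6 (1.23, SE 0.23, adjusted p = 0.0199), Dab2 (1.15), Mei4 (1.79), Dennd5b (1.18), Ndrg1 (1.15), Cav2 (1.13), Tnfsf13os (1.10) and Mid1 (1.08). Probe sets not used differed by -0.05 for Cav2, 0.07 for Dennd5b, 0.15 for Dab2, 0.21 for Tnfsf13os and -0.24 for Runx3, and 1 of 4 for Tgm2 by -0.11. In this fit no batch held both groups, so the batch block linked them through MIB control, and limma then called 0 genes, with 1492 at unadjusted p under 0.05. The blocked log2 fold changes of Runx3 (-1.98, adjusted p = 0.0656), Ifngr2 (-2.30, adjusted p = 0.102), Ifit1 (-2.56, adjusted p = 0.187) and Nrp1 (1.11, adjusted p = 0.306) had the same signs, as did those of all 267 genes, while that of Vwf was -0.54. Leaving out a further array gave 36 genes (ACD mutant replicate 2), 54 (INV16 replicate 2), 78 (INV16 replicate 1), 81 (ACD mutant replicate 1), 114 (ACD mutant replicate 3) and 505 (MIB control replicate 7).

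Grouped by the fixed lists without INV16 replicate 4, camera called 8. Interferon response genes were lower in INV16 (median -0.49, adjusted p = 1.47e-06, adjusted p = 0.419 with an estimated correlation), with 0 higher and 3 lower over all genes and 0 higher and 11 lower adjusted over the list alone. It alone was called with the batch as a block (-0.67, adjusted p = 3.81e-06, adjusted p = 0.779 with an estimated correlation). Monocyte and macrophage genes were lower (median -0.54, adjusted p = 0.000240, adjusted p = 0.419 with an estimated correlation), including Irf8 (-1.50, SE 0.30, adjusted p = 0.0259) and the lysozyme Lyz1 (-1.33, adjusted p = 0.0304), with 8 lower adjusted over the list alone and a blocked median of -0.41. Megakaryocyte genes were lower as well (-0.85, adjusted p = 0.000240, adjusted p = 0.419 with an estimated correlation; 8 lower adjusted over the list alone), but the blocked median was -0.14. The blocked medians here rest for the ACD mutant on MIB control replicates 6 and 7, which differed for several lists. RUNX1/CBF targets (-0.46, adjusted p = 0.0419), genes studied in CBFB-MYH11 leukaemia (-0.46, adjusted p = 0.0159) and p53 response genes (-0.27, adjusted p = 0.0471) were lower, each at an adjusted p = 0.419 with an estimated correlation, and their blocked medians were -0.12, -0.12 and -0.16. Of the leukaemia genes Mn1 (-0.84, adjusted p = 0.0156) and Plagl2 (-0.78, adjusted p = 0.0202) passed, and Cebpa (-0.91, adjusted p = 0.0602) did not; the other probe sets of Plagl2 differed by -0.15 to -0.39. Adjusted over the list alone 0 were higher and 6 lower, against 0 and 4 of both the RUNX1/CBF targets and the p53 genes. Erythroid genes were lower (15 genes, -0.34, adjusted p = 0.0496, adjusted p = 0.624 with an estimated correlation), with Nfe2 and Zfpm1 (-1.38, adjusted p = 0.0433, another probe set at -0.38) passing, 0 higher and 4 lower adjusted over the list alone and a blocked median of 0.04. G2 and mitosis genes were higher (0.13, adjusted p = 0.0356, adjusted p = 0.419 with an estimated correlation), with 0 members passing over all genes and a blocked median of 0.01. Leaving out a further array ended the call of the leukaemia list for INV16 replicate 3, of RUNX1/CBF targets for INV16 replicate 1 or 2 or ACD mutant replicate 3, and of G2 and mitosis for INV16 replicate 1 or 3 or ACD mutant replicate 3. The p53 and erythroid lists kept theirs in 5 of 11 such fits. Further members that passed were Cdkn1c (-0.95, adjusted p = 0.0397), Rb1 (-0.55, adjusted p = 0.0416), the class II gene H2-Aa (-1.46, adjusted p = 0.0277), Prkdc (-0.61, adjusted p = 0.0411), Rab44 (-0.60, adjusted p = 0.0356) and Hoxa7 (0.76, adjusted p = 0.0423).

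The fold changes of INV16 and of the ACD mutant against the same MIB control arrays correlated across genes at r = 0.406 with all 12 arrays, where genes are not independent replicates. Unchanged groups simulated against those controls gave a mean r of 0.237 (0.209 to 0.266 over 50 draws), and splitting the controls in 10 ways gave a mean r of 0.263 (0.159 to 0.372). The covariance was 0.0437 against 0.0119 simulated, a difference of 0.0318. With the batch as a block r was -0.424, against 0.283 (0.248 to 0.306) in groups simulated without change and fitted with the same block. That block rests in part on INV16 replicate 4, the only INV16 array of batch B. In the 11 arrays without INV16 replicate 4, r was 0.342 against 0.487 simulated. The covariance was 0.0230 against 0.0121, a difference of 0.0109, and the split controls gave a mean r of 0.158 (-0.0936 to 0.327). The block left these 11 arrays with separate controls for each comparison, and r was then 0.301, against -0.000320 simulated (-0.0316 to 0.0394), with a covariance of 0.0209. In the simulated draws genes vary independently, unlike on real arrays, so their ranges are too narrow. Deviations of single INV16 and ACD mutant arrays from their group means correlated at -0.309 to 0.416 in these 11 arrays. The draws here and above thus cannot decide whether r lies beyond chance. In those 11 arrays 9 genes were lower than MIB control in both groups, where independent lists would share 0.983: Cd72, Chn2, Dipk1b, Gem, Helq, Med7, Rpl12, S1pr3 and Zc3h8. The 6 genes higher in both, against 0.803 for independent lists, were Dnajc3, Fbp1, Hlx, Kdm5b, Selp and Sertad2. The figures for independent lists leave out the shared MIB control arrays. When these arrays were split between the comparisons in 20 ways, a mean of 1.30 genes (0 to 10) were higher and 2.30 (0 to 16) lower in both. Selp alone was higher in both by the probe set used, and Gem alone lower, with the batch as a block. INV16 was lower than both other groups in 63 genes (2.42 for independent lists), among them Runx3, Gse1, Nfe2, Mn1, Tfr2, Fut7, Fam43a and Piezo1. It was higher than both in 14 (0.251), among them Nrp1, Il6 and Dab2. These comparisons share the INV16 arrays, and without INV16 replicate 4 all of these lay in batch A and all ACD mutant arrays in batch B. With the batch as a block 0 genes were called in INV16 against the ACD mutant, so 0 of the 63 and 0 of the 14 remained, although all 267 genes kept their sign and Runx3 went from -1.49 to -1.98. With all 12 arrays, where INV16 replicate 4 lies in batch B, the block left 4 genes lower in INV16 than in both other groups, namely Btnl9, Fam43a, Foxred2 and Gse1, all among the 63. Batch B then holds no other INV16 array, so these 4 lean on replicate 4, whose source stays open. The lists of shared genes were drawn up after their values were seen.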

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

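The tests of technical explanations and the counts of other splits were chosen only after the results they bear on had been seen; the comparison of each extreme array with its group and of INV16 with the ACD mutant were set beforehand. An array was singled out where its gap to the nearest array of its group, divided by the group's range, passed Dixon's critical value. Chance does so in about 1 of 20 groups. Of 212 values tested, 106 in each of the INV16 and MIB control groups, 37 passed, 32 of them in INV16, and in 31 of these INV16 replicate 4 was the array apart.

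INV16 replicate 4 was the lowest array for Aurkb (ratio 0.936), Bub1b (0.97), Cad (0.89), Ccna2 (0.941), Cdc25c (0.981), Cdkn1c (0.91), Cebpa (0.921), E2f1 (0.885), Foxred2 (0.862), Gar1 (0.87), Lig1 (0.85), Lyz2 (0.926), Pf4 (0.843), Pole (0.911), Snhg12 (0.891), Spns3 (0.864) and Wdr12 (0.898). It was also lowest for the lists DNA repair (0.921), G2 and mitosis (0.985), Hox and Meis (0.863), ribosome biogenesis and Myc targets (0.931) and S phase (0.952), and for BioC minus BioB (0.966). It was the highest for Cma1 (0.97), Hdc (0.831), Klf2 (0.889), Klf6 (0.949), the lists erythroid (0.893), immediate early (0.867) and mast cell (0.976), and the Gapdh 3' minus 5' difference (0.8293).

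The first pattern is the distance of INV16 replicate 4 from the other 11 arrays. A mixture in which progenitors like those of the other INV16 arrays remained a sizeable part is argued against by 71 genes that lie over 4 log2 under every other array; degraded RNA is argued against by 35 genes that lie over 4 log2 above every other array, against 0 in ACD mutant replicate 1, whose Gapdh difference was also raised. Of the arrays of the other groups, 0 had Xist above Eif2s3y. This cannot decide on a swap with 1 of them, since an INV16 sample in its place may have low Xist, like INV16 replicates 1 to 3. A sample of another cell population from a female animal, a wrong label or a swap with a sample inside or outside the series stay open, as does a very small residual share of progenitors. Mast cell genes as a list deviated by a median of 4.18 log2 (12 of 13 higher), with Cpa3 at 14.27, Hdc at 13.95 and Ms4a2 at 13.67. The filter over all 12 arrays admits genes high on this array alone, such as Fcer1a and Cma1, so these list values rest in part on that selection. Mast cells are a candidate source of this RNA, though Cpa3, Hdc and Ms4a2 measured 7.76 to 11.38 on the other arrays. The CD45 gene Ptprc, picked after its value was seen, was lower than on all of them, at 8.01 against 11.84 to 12.44. The sort on Sca-1 would remove cells without that marker, and no biological explanation was tested.

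The second pattern is the higher level of interferon response genes in the ACD mutant. The spike-in batch as the whole cause is argued against by the list's median of 0.61 with the batch as a block, against 0.53 without it, and 0.60 or 0.61 when MIB control replicate 6 or 7 was left out as well. The raised Gapdh difference of ACD mutant replicate 1 is argued against by the median of 0.68 without that array, but the height rests heavily on replicate 2, at 1.22 for the list's mean against 0.47 and 0.45 in replicates 1 and 3, and without it the median was 0.30, called by camera at its preset correlation but not with an estimated one (adjusted p = 0.0617). Within batch B the spike-in BioB still parted the ACD mutant arrays (7.13 to 7.49) from MIB control replicates 6 and 7 (8.57 and 8.76). The block cannot remove a technical difference along that split. Such a difference, a response to the mutant protein, and a difference in viral load or in the transduction between groups stay open and untested. In MIB control, replicate 5 had the highest Ifit1 (ratio 0.764).

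The third pattern is the higher level of megakaryocyte genes in the ACD mutant against MIB control. The list's median was 0.64 pooled and 0.15 with the batch as a block, but this value rests on MIB control replicate 7, where the list's mean lay at 0.90 against 0.003 in replicate 6, the other control of that batch. Without replicate 7 the blocked median was 0.71, and without replicate 6 it was -0.27. The spike-in batch, a deviation of MIB control replicate 7 alone and an effect of the mutant cannot be told apart with 2 controls in that batch, and all stay open.

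Other splits of the same arrays bear on each count of called genes. For INV16 against MIB control, 1 of 100 splits, the real one, gave as many as the real 20 genes, the highest other being 2, and without INV16 replicate 4 it was 1 of 56, with 219 and 190. Groups simulated without change, each at its own spread, gave a mean of 48.1 genes (highest 82) with 12 arrays, where replicate 4 widens the spread of INV16, and 1.02 (highest 6) without it, but they hold no difference between batches. The 190 genes part MIB control replicates 5 to 7 from the rest, and the next split, with 137 genes, MIB control replicates 6 and 7 and INV16 replicate 3 from the rest. Both keep the 2 controls of batch B together, so part of the 219 may follow the batch. Under the batch block the real count was 148, the only other split with as many was its mirror, which parts batch A in the same way, and the highest of the others was 40; batch A alone gave 30. Without a batch effect the splits argue against chance for the 219 genes, where 1 of 56 is the smallest share they can give. With one, only arrays of the same batch can be exchanged, and all INV16 arrays here lie in batch A. The splits cannot settle that case, so the share due to batch or chance stays open. For the count of 20 the simulation cannot decide. It spreads all 4 INV16 arrays alike, while the data hold 1 array far from the other 3. All 20 genes were called again without replicate 4, but chance was not excluded for this count. For INV16 against the ACD mutant 1 of 35 gave as many as 5, the highest other being 2. Simulated groups without change gave a mean of 11.98 genes (highest 33), but they too spread all INV16 arrays alike. They cannot decide here either, and chance was not excluded. Without INV16 replicate 4 there are 10 splits, too few for a share under 0.05, with 267 genes and a highest other of 0. For the ACD mutant against MIB control the real count was 0, so all 56 of 56 splits had to give at least as many (highest other 1), and the splits say nothing. Without INV16 replicate 4, 2 of 56 splits gave 220 or more; the other gave 1057 genes, parts MIB control replicates 3 to 5 from the rest, and so follows the spike-in batch. It points to a structure of the samples, and with the batch as a block the real count was 20, which 1 of the 55 splits that could be fitted, the real one, reached (highest other 13). With a batch effect only arrays of the same batch can be exchanged, and all ACD mutant arrays lie in batch B. These splits therefore cannot settle chance for the 20 genes, a count that fell to 1 without MIB control replicate 7.

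The difference between INV16 and the ACD mutant, whose effects are each set against MIB control, passed the test for Fam43a (-1.61), Foxred2 (-1.16), Gse1 (-1.48), Piezo1 (-0.91) and Prkd2 (-1.08). It also passed camera for the lists cholesterol synthesis (-0.58), DNA repair (-0.40), G2 and mitosis (-0.47), genes studied in CBFB-MYH11 leukaemia (-0.30), immediate early (0.75), interferon response (-0.68), long-term stem cell (-0.40), megakaryocyte (-0.87), monocyte and macrophage (-0.67), ribosome biogenesis (-0.45), RUNX1/CBF targets (-0.78) and S phase (-0.55). With an estimated correlation 0 of these 12 lists were called. Leaving out INV16 replicate 4 turned G2 and mitosis to 0.13 and ended the calls of cholesterol synthesis (-0.20), DNA repair (-0.14), S phase (-0.04), ribosome biogenesis (0.03), immediate early (0.11) and long-term stem cell genes (-0.31). Prkd2 and Piezo1 lost their call with the batch as a block (each at adjusted p = 0.0787). The list of cell cycle inhibitors (0.99) was lowest in INV16 replicate 3. In MIB control, replicate 3 was highest for Flt3 (0.764), Mn1 (0.753) and Ptcd1 (0.821), and replicate 7 for Pf4 (0.761).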

How the results depend on the processing

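The fits without INV16 replicate 4 and with the spike-in batch as a block were chosen only after the results were seen. The other alternatives on 12 arrays were planned. With 12 arrays the batch block rests in part on INV16 replicate 4, the only INV16 array of batch B. For single named genes with 12 arrays, 1013 of the alternative values kept direction and side of the threshold, 63 now passed, 50 no longer passed and 16 reversed, and leaving out single arrays gave 1113, 26, 109 and 12. With 11 arrays these counts were 1182, 38, 217 and 8, and 1074, 22, 361 and 6. None of the genes that reversed had passed the test. Except where the alternative is itself a change of threshold, of the genes tested or of the arrays used, the cause of each change was not tested. Values near the filter of 5.10 carry little signal over background, so changes of dim genes are measured less well, and floors for linear values were not run since the values were log2.

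With 12 arrays, the 20 genes of INV16 against MIB control became 7 after quantile normalisation, 45 with all probe sets, 1 in a fit to only the groups compared, 10 with an intensity trend, 1471 with array weights (which gave INV16 replicate 4 a weight of 0.0400), 73 with the batch block and 55 at an adjusted p under 0.10. The 0 genes of the ACD mutant against MIB control (892 at unadjusted p under 0.05 by limma) became 5 with all probe sets, 72 in the fit to those groups and 944 with array weights, and stayed 0 under the other planned settings. The 5 genes of INV16 against the ACD mutant became 22 when each array was median-centred, 14 with all probe sets, 13 with the mean of probe sets, 0 in the fit to those groups, 3 with an intensity trend, 2077 with array weights and 28 at an adjusted p under 0.10. Leaving out single arrays gave 1 (without MIB control replicate 5, among others) to 219 (INV16 replicate 4), 0 to 220 (INV16 replicate 4) and 0 (ACD mutant replicate 1) to 267 (INV16 replicate 4) genes. Of the 25 lists, the 6 called in INV16 against MIB control became 3 with array weights and 0 with an estimated correlation or fry, and 0 (without INV16 replicate 4) to 10 (INV16 replicate 3) without single arrays. The 4 lists of the ACD mutant against MIB control became 7, 0 and 2 with array weights, estimated correlation and fry, and 3 to 6 without single arrays. The 12 lists of INV16 against the ACD mutant became 5, 0 and 3, and 8 to 13 without single arrays.

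With the 11 arrays that exclude INV16 replicate 4, the 219 genes of INV16 against MIB control became 332 with all probe sets, 93 in the fit to those groups, 1640 with array weights and 407 at an adjusted p under 0.10, and 29 (without INV16 replicate 1) to 332 (MIB control replicate 4) without single arrays. The 220 genes of the ACD mutant against MIB control became 142 when median-centred, 421 with all probe sets, 72 in the fit to those groups, 996 with array weights, 20 with the batch block and 788 at an adjusted p under 0.10, and 3 (ACD mutant replicate 1) to 591 (MIB control replicate 7). The 267 genes of INV16 against the ACD mutant became 173 with the mean of probe sets, 840 in the fit to those groups, 2338 with array weights, 0 with the batch block (1492 at unadjusted p under 0.05 by limma) and 794 at an adjusted p under 0.10, and 36 (ACD mutant replicate 2) to 505 (MIB control replicate 7). The 0 lists of INV16 against MIB control became 2 with no filter, 3 with array weights, 2 with the batch block and 1 with fry, and 0 to 10 (INV16 replicate 3), with 3 without MIB control replicate 7 and 1 without INV16 replicate 1. The 6 lists of the ACD mutant against MIB control became 0 with an estimated correlation and 2 with fry, and 5 to 8 without single arrays. The 8 lists of INV16 against the ACD mutant became 1 with the batch block and 0 with an estimated correlation or fry, and 4 (INV16 replicate 3 or ACD mutant replicate 3) to 10 (MIB control replicate 7).

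The correlation of fold changes, 0.406, reversed to -0.424 with the batch block (0.283 in simulated groups without change) and was 0.301 with that block on 11 arrays (-0.000320 simulated). It ran from 0.342 (without INV16 replicate 4) to 0.462 (MIB control replicate 7) without single arrays. With 11 arrays it ran from 0.289 (INV16 replicate 1) to 0.403 (MIB control replicate 7). The simulated values come from independent genes and cannot decide on chance.

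Genes whose direction reversed, in log2 fold change with 12 arrays, were as follows. With array weights they were Cd34 (0.29) and Tpsb2 (-0.021) in INV16 against MIB control, Kit (0.032) in the ACD mutant against MIB control, and Cbfb (0.27) and Cd34 (0.62) in INV16 against the ACD mutant. With the batch block they were Flt3 (-0.043) in the first, Cbfb (0.11), Cd34 (0.78) and Flt3 (0.19) in the next, and Flt3 (-0.23) and Runx1 (0.35) in the last comparison. With the mean of probe sets they were Kit (0.18) in the ACD mutant against MIB control and Runx1 (0.057) in INV16 against the ACD mutant. Without single arrays, INV16 against MIB control ran from -1.44 to 0.22 for Cd34 and -0.30 to 0.38 for Flt3 (INV16 replicate 2 and 4 left out), and -0.32 to 0.00066 for Kit (INV16 replicate 2 and 3). Kit in the ACD mutant against MIB control ran from -0.15 to 0.083 (ACD mutant replicate 3 and 1). INV16 against the ACD mutant ran from -0.23 to 0.25 for Cbfb, -1.10 to 0.55 for Cd34 and -0.097 to 0.59 for Flt3 (INV16 replicate 2 and 4), and -0.29 to 0.043 for Kit (ACD mutant replicate 1 and INV16 replicate 3). With 11 arrays Kit reversed in the ACD mutant against MIB control with the mean of probe sets (0.18), array weights (0.032) and the batch block (0.047), and Cbfb in INV16 against the ACD mutant with the batch block (-0.019). Without single arrays Cbfb ran from -0.11 to 0.026 and Kit from -0.44 to 0.047 in INV16 against MIB control, Kit from -0.15 to 0.083 in the ACD mutant against MIB control and from -0.39 to 0.089 in INV16 against the ACD mutant (for INV16, replicates 2 and 3 left out).

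Whether the replicate numbers pair the samples stays open. With 12 arrays, the deviations of INV16 and ACD mutant arrays with the same number correlated at -0.227, -0.172 and 0.0740. Those of MIB control and INV16 correlated at -0.00163 and -0.0992, and of MIB control and ACD mutant at 0.0931. Arrays with different numbers ranged from -0.301 to 0.424. Without INV16 replicate 4 the first values were -0.161, -0.181 and -0.309, and replicate 3 of MIB control and INV16 gave -0.332. No pair with the same number correlated highly, but so few pairs cannot exclude pairing. With the replicate block the counts of genes were 0, 0 and 0 in INV16 against MIB control, the ACD mutant against MIB control and INV16 against the ACD mutant, and 1, 24 and 380 without INV16 replicate 4. The lists called were 6, 9 and 7, and 0, 5 and 10 without that array. Under the block Flt3 (-0.68) in INV16 against MIB control and Cbfb (0.16) and Cd34 (0.18) in INV16 against the ACD mutant reversed, and with 11 arrays Cd34 (-0.12), Flt3 (-0.71) and Runx1 (-0.77) in INV16 against MIB control and Runx1 (-0.038) in the ACD mutant against MIB control.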

Other observations

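The values in this part without INV16 replicate 4 and by spike-in batch were chosen only after the data were seen; the gene lists were fixed beforehand. Without that array, camera called 0 of the 25 lists in INV16 against MIB control (6 at unadjusted p under 0.05) and fry called 1, DNA repair (-0.18, adjusted p = 0.0247). The count by camera was 10 without INV16 replicate 3, 3 without MIB control replicate 7 and 1 without INV16 replicate 1, as named in the report. Erythroid genes had a median log2 fold change of -0.27 (15 genes, 1 lower, camera adjusted p = 0.150), monocyte and macrophage genes -0.32 (18 genes, 0 called, 0.150) and neutrophil granule genes -0.28 (19 genes, 1 lower and, adjusted over the list alone, 1 higher and 4 lower, 0.338). Within batch A alone these medians were -0.06, -0.19 and -0.05. Immediate early genes were at 0.17 (0.274), inflammatory cytokines at 0.03 with 1 higher (0.150), stromal and endothelial genes at 0.14 with 1 lower (0.273), p53 response genes at 0.18 (0.132), ribosome biogenesis at -0.14 (0.150), S phase at -0.10 (0.0948) and G2 and mitosis at -0.07 (0.487). Within batch A immediate early genes were at 0.10, inflammatory cytokines at 0.02 and ribosome biogenesis at -0.03. The sort markers, 9 genes, were at 0.08 (0.350), mast cell genes at -0.18 (0.603), dendritic cell genes at -0.09 (0.732), the CBF complex and ETO family at -0.05 (0.934), lymphoid genes at 0.11 (0.150), and cholesterol synthesis at 0.02 and unfolded protein stress at 0.001 (0.658 and 0.684). Within batch A sort markers were at 0.16, mast cell genes at -0.09, dendritic cell genes at -0.04, the CBF complex at -0.02, cholesterol synthesis at 0.15 and unfolded protein stress at 0.02. There megakaryocyte genes turned from -0.18 pooled to 0.08 and long-term stem cell genes to 0.05. For long-term stem cell genes (median -0.09, mean 0.04, 0.658), Hox and Meis genes (median 0.13, mean -0.01, 0.516), cell cycle inhibitors (median -0.03, camera direction up, 0.942) and interferon response genes (median -0.01, camera direction up, 0.732) the median, the mean and the test differed in sign. After quantile normalisation or median-centring, the medians of cell cycle inhibitors, cholesterol synthesis, inflammatory cytokines and unfolded protein stress turned sign.

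The MIB control arrays themselves differed. Batch B exceeded batch A by a median of 0.54 log2 in erythroid genes, 0.46 in cholesterol synthesis, 0.39 in genes studied in CBFB-MYH11 leukaemia, 0.34 in long-term stem cell genes, 0.30 in dendritic cell genes and 0.24 in mast cell genes, while interferon response (-0.01), p53 response (-0.09) and G2 and mitosis (-0.08) differed by under 0.1. Batch B held only replicates 6 and 7, and replicate 7 carried most of several gaps: without it they were 0.17 in erythroid genes, 0.23 in cholesterol synthesis, 0.20 in the leukaemia genes, 0.07 in long-term stem cell genes and 0.01 in mast cell genes, and 0.33 in dendritic cell genes. Other gaps grew without replicate 7, from 0.22 to 0.65 in neutrophil granule genes and from 0.22 to 0.51 in RUNX1/CBF targets. That of monocyte and macrophage genes went from 0.17 to 0.49. Without replicate 6 these gaps were -0.26, -0.16 and -0.18. Batch and single array cannot be told apart in these values. limma called 0 genes between these MIB control arrays, with 2533 of the 12918 at unadjusted p under 0.05. In the ACD mutant against MIB control within batch B alone, 42 genes were called, 25 higher and 17 lower, and 19 of them were among the 220 called in the 11 arrays.

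Runx3 and Gse1 were low on INV16 replicate 4 as on the other INV16 arrays, an observation made after the values were seen. Runx3 measured 8.86 there and 8.28, 8.36 and 8.97 on the others, and Gse1 7.19 against 7.93, 7.62 and 7.59. No test bears on whether that array holds cells with the fusion.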
